A study of Mus musculus with 2 samples.

How the data were processed

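Single-cell RNA was measured with the 10x Genomics 3′ v3.1 chemistry in thymocytes enriched with anti-CD25 beads, in 1 library from WT mice and 1 library from SETDBf/fCD4-Cre mice (cKO). The deposited matrices hold raw UMI counts per gene and cell barcode, and per the file headers they were written by Cell Ranger 6.1.1. The submitters' processing notes also name CASAVA 1.8 and Seurat 4.0.3, and no Seurat object was used here. The genome build is not given in the sources used here, so no coordinates are given. Gene types and the Y chromosome were looked up by gene identifier in GENCODE vM21 on GRCm38, which held 31107 of the 31253 genes of the files. The number of animals behind each library is not given either.

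Barcodes with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs were taken. Doublets were scored by scrublet as built into scanpy 1.11.5, per library, with an expected rate of 0.06. The automatic threshold was 0.29 in the WT library and 0.638 in the cKO library, where it called 1 of 7501 barcodes. The WT threshold was therefore used for both libraries, a choice made after this failure was seen, and 148 WT and 129 cKO barcodes were removed as doublets. This left 6989 WT cells with a median of 7700 UMIs and 7372 cKO cells with a median of 4653 UMIs.

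Cells of both libraries were clustered together in Python 3.11.15 with scanpy 1.11.5 and python-igraph 0.11.9. Counts were scaled per cell and log-transformed, 2000 variable genes without TCR and Ig segments were taken, and 30 principal components, 15 neighbours and Leiden resolution 1 were used without batch integration. A cluster took the name of a class when its markers lay on average at least 0.4 log2 above the other clusters, at least 3 markers were at least 2-fold higher and detected in at least 10% of its cells, and no other class had more markers among its top 10 genes. The marker lists were fixed before the data were examined, and these naming thresholds were set after clusters had been seen. Classes carry the suffix -like because they rest on RNA alone. Clusters with more than 50% of cells holding Trac and fewer than 50% holding Rag1 formed a mature subset, which was clustered again without the cell cycle lists and the genes that differed 1.5-fold or more between libraries, 330 genes in all. This second clustering was added after the data had been seen.

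An earlier clustering had also left out sex-linked genes, against the design, and its results had been seen before the designed set of variable genes was used. That change replaced 1 of the 2000 variable genes (Gm47283, with Apobec1 in its place) and moved the border of the Treg-like class, so the earlier version and 2 other Leiden seeds are kept as alternatives. The designed version is the one reported. After that change the Treg precursor-like class was taken from the clustering of all cells rather than from the mature subset.

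UMIs were summed per class and library in classes with at least 100 kept cells per library and scaled to the sum of the class (CPM). Folds are log2 of (CPM cKO + 5)/(CPM WT + 5). Shares carry 95% Clopper-Pearson intervals, sums carry exact Poisson intervals, and ratios of sums or shares carry the exact binomial interval of the 2 counts. These intervals cover counting error only, and do not cover differences between mice, bead enrichments or captures. With 1 library per genotype no test between genotypes was possible, so no p-value and no number of changed genes is given. A gene with 0 UMIs in one library was compared with a floor of 3 counts over the class.

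Shares of cells with at least 1 Foxp3 UMI, or at least 1 Mki67 or Top2a UMI, were taken after each cell was thinned to 2000 UMIs, and cells below that depth were left out. The depth was chosen after the depths of the cells were known and before any thinned share was computed. For gene lists fixed before the data were examined, the median fold of members with at least 20 UMIs in the class was taken relative to the median of all such genes, as were counts of members at least 1.5-fold higher or lower. Its percentile among 10000 random lists matched on size and expression describes these 2 libraries and is no p-value. The lists were Treg signature, IL-2 and STAT5 response, TCR and agonist signalling, proximal TCR signalling components, thymocyte maturation and egress, interferon-stimulated genes, apoptosis regulators, p53 targets, germline genes, Fc receptors and adaptors, type 1 effector genes, type 2, type 17 and helper genes, the DN and Notch program, V(D)J recombination and DP program, S phase, G2 and M phase, H3K9 methylation and HUSH machinery, genes derived from retroviral elements, dissociation and heat-shock stress, oxidative phosphorylation, glycolysis and MYC targets, cholesterol and lipid synthesis, unfolded protein and integrated stress response, chemokine receptors and adhesion, and free RNA and other cell types.

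The rule for named genes was fixed before the data were examined. In each class it takes the 10 genes with the highest and the 10 with the lowest fold among those with at least 100 UMIs over both libraries and at least 50 CPM in one of them. It leaves out TCR and Ig segments, mitochondrial, Xist, Tsix and Y-linked genes, and gene models named Gm plus digits or ending in Rik, which were looked at apart. Setdb1, Setdb2, Foxp3, Il2ra, Cd4, Cd8a, Cd8b1, Fcgr2b, Bcl2 and Bcl2l11 are always taken, with 2 to 4 members per list. Not all of these are printed below for every class and list.

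The calculation was tested on simulated sums with known folds, drawn as Poisson counts from the Treg-like, DN-like and DP-like profiles pooled over both libraries. The intervals assume the same counting error, so this checks the calculation and not spread between cells or mice. Intervals covered the true ratio for 95.5% to 95.8% of genes without a difference, and for 90.0% to 100% of the 50 genes given each planted fold per class, lowest for 2-fold higher genes in DN-like cells. A true log2 fold of 1 gave medians of 0.95, 0.88 and 0.93 in the 3 classes. Larger folds downward were shrunk more by the pseudocount, since a true log2 fold of -2 gave medians of -1.66, -1.47 and -1.68 in the same order. Between 1.5% and 3.5% of null lists fell outside the middle 95%, and 100% of planted lists were found. Most members of a planted list were 2-fold higher, so this does not show that smaller list medians would be found.

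Other settings chosen before the data were examined were a looser and a stricter cell filter, doublets kept, Leiden resolution 0.5 and 2, classes defined on WT cells, clustering without differing and cycle genes, TMM factors (edgeR 4.0.16 in R 4.3.3), sums without mitochondrial, ribosomal and haemoglobin genes, means of per-cell CPM, cells without Mki67 or Top2a UMIs, other pseudocounts and list minimums, and Treg cells taken as T-lineage cells with a Foxp3 UMI. Added after seeing the data were the automatic doublet thresholds, other thinning depths, Treg-like cells without Ptcra, Dntt, Rag1 or Rag2 UMIs, Treg-like and Treg precursor-like clusters of the mature subset, the mature subset clustered with all variable genes, the version with sex-linked genes left out, 2 other Leiden seeds, and DN-like cells without an interferon-high cluster. Where a setting redrew the clusters, each cluster took the class that most of its cells had in the reported clustering. The marker rule was applied again only to the mature subset clustered with all variable genes. With classes defined on WT cells, cKO cells took the class of their nearest WT cells. Sums and intervals used numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.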

Results

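Thymocytes enriched with anti-CD25 beads were profiled in 1 WT library and 1 SETDBf/fCD4-Cre library (cKO). CD25 marks both early double-negative (DN) thymocytes and regulatory T cells (Treg). CD4-Cre acts from the end of the DN stage on, so DN-like cells serve as the comparator taken to have formed before the deletion. That order was not measured here. The label does not say whether Setdb1 or Setdb2, which encode relatives among the histone H3K9 methyltransferases, is floxed. The files held 7852 WT barcodes with 89370968 UMIs and 8461 cKO barcodes with 76668166 UMIs. The kept cells had a median of 2596 genes in WT and 1861 in cKO, and the median mitochondrial share was 4.48% in both. There are no replicates, and every interval covers counting error only.

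The first comparison asks which cells made up the enriched suspension. DP-like cells, the CD4 and CD8 double-positive stage, made up 29.7% of WT cells (28.6 to 30.7) and 41.8% of cKO cells (40.7 to 42.9), a ratio of 1.41 (1.33 to 1.49). DN-like cells made up 17.3% of WT and 10.8% of cKO cells, a ratio of 0.622 (0.568 to 0.681). Treg-like cells made up 6.28% of WT and 6.55% of cKO cells, a ratio of 1.04 (0.915 to 1.19). Their ratio depended on the denominator: it was 1.17 (1.02 to 1.33) without DN-like and DP-like cells. In the mature subset, clustered again after the data had been seen, they numbered 377 of 872 and 388 of 1070, a ratio of 0.839 (0.726 to 0.969), which was 0.559 (0.472 to 0.661) with all variable genes and 1.001 with classes defined on WT cells. With all variable genes 120 WT and 298 cKO cells of the subset were unnamed, against 134 and 199 before. The subset also held 85 WT and 154 cKO DP-like cells. These ratios thus depend on which cells are named and counted, and do not show a loss of Treg cells. Treg precursor-like cells, which carried agonist-signalling genes with little Foxp3, numbered 175 of 6989 and 191 of 7372 (ratio 1.04, 0.838 to 1.28). No class was named for 42.1% of WT and 36.6% of cKO cells. Among these, a cluster of 712 WT and 679 cKO cells had the DN markers Notch1, Notch3, Hes1, Mpzl2 and Cd24a raised. The DN-like class may thus miss DN cells, and the denominators without DN-like cells still held this cluster. DN-like shares were 10.5% of WT and 6.80% of cKO cells with another Leiden seed. With sex genes left out they were 21.95% and 14.7%. The bead enrichment sets these shares, so they are not shares of the thymus. With differing and cycle genes left out of the clustering, DP-like cells had a ratio of 1.43 and DN-like cells 0.708.

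**Figure D1:**
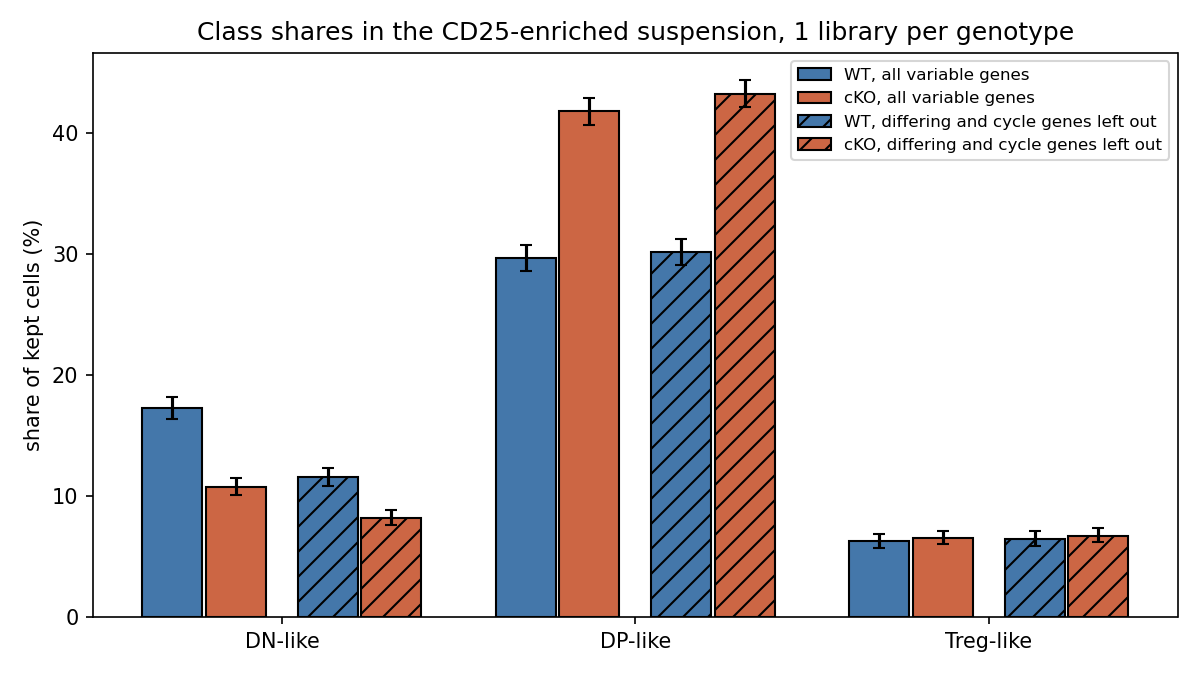
Share of kept cells (%) in 3 classes for WT (blue) and cKO (red), from the clustering with all variable genes (plain) and without differing and cycle genes (hatched). Error bars are 95% Clopper-Pearson intervals, which cover counting error only; DP-like cells took 29.7% of WT and 41.8% of cKO cells, and Treg-like cells 6.28% and 6.55%.

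Foxp3, the transcription factor that defines Treg cells, gave shares that do not rest on clusters. After thinning, 3.06% of WT cells (197 of 6441) and 2.95% of cKO cells (182 of 6172) held a Foxp3 UMI, a ratio of 0.964 (0.784 to 1.18), which was 1.35 when cells were thinned to 3000 UMIs. Without thinning the shares were 4.74% and 4.48%. Inside the Treg-like class 34.4% of WT and 38.5% of cKO cells were positive after thinning, at median depths of 5520 and 5162 UMIs. As background, 0 of 46 WT and 1 of 45 cKO B-like cells were positive, at median depths of 3390 and 3773.5 UMIs, and 0 of 1205 WT DN-like cells, which allows a share of up to 0.306%. Thinning left out 548 WT and 1200 cKO cells, of which 479 and 1100 were DP-like. Without thinning, 3 of 2072 WT and 5 of 3081 cKO DP-like cells held a Foxp3 UMI. The thinned share of all kept cells thus depends on how many such cells the depth removes from each library.

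Effector Treg-like cells, which carry genes such as Klrg1 and Il1rl1, formed a cluster of 66 WT and 54 cKO cells among all kept cells (share ratio 0.776, 0.531 to 1.13). This cluster was mixed, since 54.5% of its WT cells and 9.26% of its cKO cells held a Foxp3 UMI. In the mature subset effector Treg-like cells numbered 39 of 872 in WT and 10 of 1070 in cKO, a ratio of 0.209 (0.0930 to 0.426). With classes defined on WT cells the ratio was 0.427. With 2 other Leiden seeds no cluster of that subset took this name, so the number depends on the clustering. Clusters there were named by the class most of their cells had in the reported clustering, not by markers.

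The main comparison concerns Treg-like cells, 439 in WT with 2819698 UMIs and 483 in cKO with 2863872 UMIs. A small set of genes was far higher in cKO, while Foxp3 itself differed little. Cfap53 (ENSMUSG00000035394), a cilium gene, stood at 0.355 CPM in WT, from 1 UMI, and 101 CPM in cKO, from 289 UMIs, a ratio of 284.5 (50.7 to 11280). Resf1 (ENSMUSG00000032712), which encodes a regulator of retroelement silencing, stood at 156 and 956 CPM, a ratio of 6.14 (5.55 to 6.81). Atf7ip (ENSMUSG00000030213), which encodes the binding partner that stabilises SETDB1, stood at 111 and 274 CPM, a ratio of 2.47 (2.17 to 2.83).

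The other genes with the highest folds under the rule for named genes were the keratin gene Krt83 (log2 2.58), Dapl1 (2.47) and the D-dopachrome tautomerase gene Ddt (2.13). They were followed by the glutathione transferase gene Gstt2 (2.0), the medium-chain acyl-CoA dehydrogenase gene Acadm (1.83), the TIF1 family gene Trim24 (1.63) and the zinc finger gene Zfp52 (1.41). Fcgr2b (ENSMUSG00000026656), the inhibitory Fc receptor gene, had 0 UMIs in WT and 43 in cKO Treg-like cells, at least 14.1-fold higher against a floor of 3 counts over the class. With the counting error of the cKO sum as well, the exact interval of the ratio starts at 11.0. Among gene models, Gm19951 (ENSMUSG00000113136) had 2 UMIs in WT and 678 in cKO, a ratio of 333.8 (92.0 to 2762). The 10 named genes with the highest folds, Cfap53 to Atf7ip, had a median log2 fold of 2.07 in Treg-like and 0.15 in DP-like cells. In DN-like cells 6 of them had at least 100 UMIs, with folds from -0.14 (Ddt) to 0.49 (Resf1). The list of H3K9 methylation and HUSH machinery genes, which includes Resf1 and Atf7ip, had a median of 0.11 in Treg-like cells with 2 of 23 members at least 1.5-fold higher, and turned to -0.03 with the stricter cell filter.

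**Figure D2:**
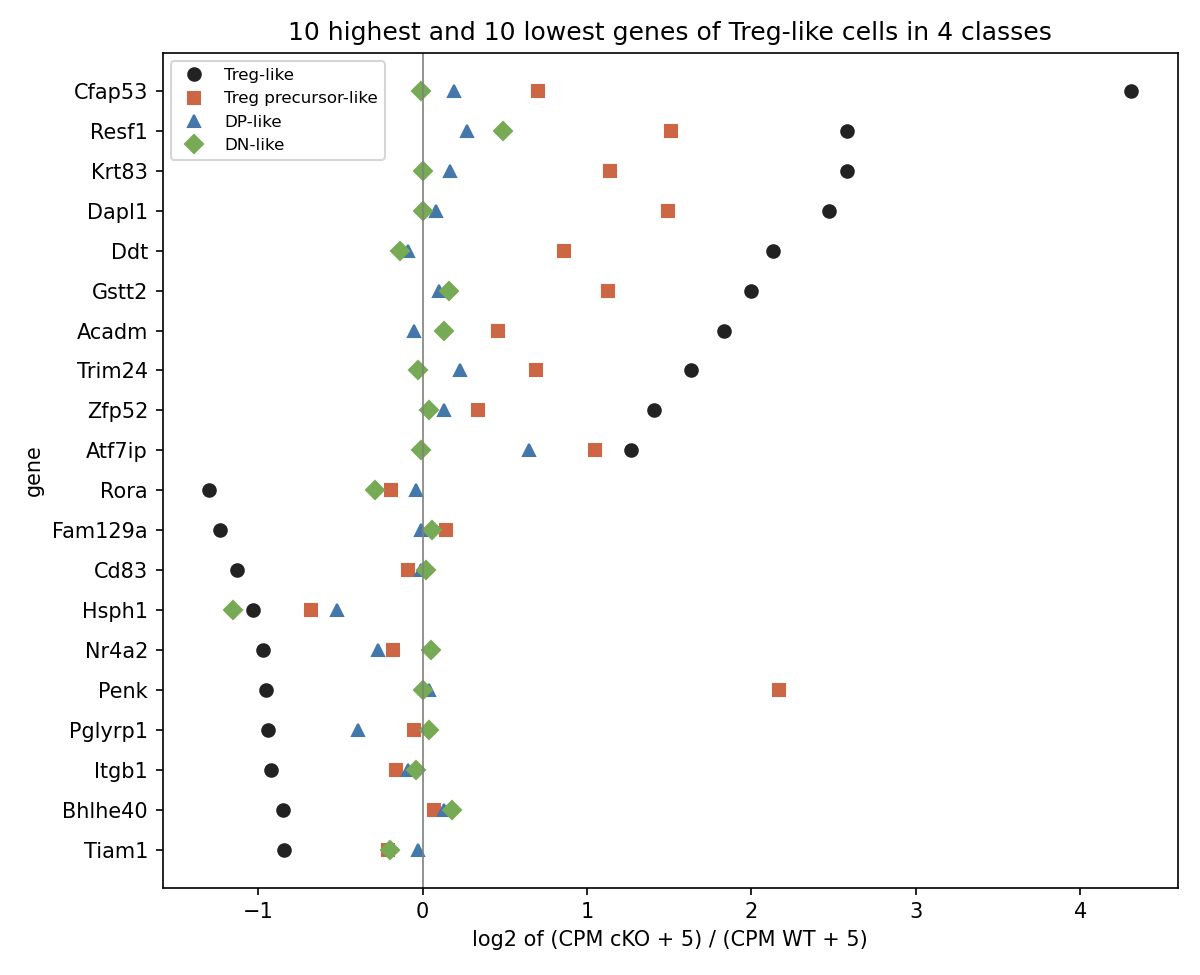
Log2 fold of cKO over WT (x axis) for the 10 highest and 10 lowest named genes of Treg-like cells (y axis), in Treg-like (circles), Treg precursor-like (squares), DP-like (triangles) and DN-like cells (diamonds). Resf1 stood at 2.58 in Treg-like and 0.49 in DN-like cells, and Hsph1 was below 0 in the 4 classes.

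Lowest in cKO Treg-like cells under the rule for named genes was Rora, which encodes a nuclear receptor. It stood at 106 CPM in WT and 40.2 CPM in cKO (log2 -1.30). Next came Fam129a (-1.23), the activation marker gene Cd83 (-1.13), the heat-shock gene Hsph1 (-1.03), the orphan nuclear receptor gene Nr4a2 (-0.97), the enkephalin precursor gene Penk (-0.95), Pglyrp1 (-0.94), the integrin gene Itgb1 (-0.92), the transcription factor gene Bhlhe40 (-0.85) and Tiam1 (-0.84). In Treg precursor-like cells Penk went the other way, with 9 UMIs in WT and 67 in cKO (2.17). In Treg-like cells Penk was above 0 under 2 of 20 alternatives, reaching 1.11 with the stricter cell filter, and Pglyrp1 under 1 of 20. Penk was also a top gene of the effector Treg-like cluster of the mature subset, and Pglyrp1 of that among all kept cells. Foxp3 stood at 254 and 268 CPM (ratio 1.05, 0.949 to 1.17), the CD25 gene Il2ra at 223 and 273 CPM (1.23, 1.10 to 1.36), Cd4 at 151 and 158 CPM, Bcl2 at 367 and 424 CPM and Bcl2l11 at 39.7 and 45.7 CPM. Cd8a had a log2 fold of 0.41 and Cd8b1 of 0.49, and both were below 0 under 3 of 20 alternatives that drew the class differently.

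Among the gene lists in Treg-like cells, dissociation and heat-shock stress genes lay lowest, with a median of -0.36 (percentile 0.0), and 4 of 18 members at least 1.5-fold lower, among them Fosb (-0.75) and Jun (-0.68). Type 2, type 17 and helper genes lay at -0.30, with Ccr6 at -0.44 and 1 of 7 members, Rora, at least 1.5-fold lower. Both genes are also markers of effector Treg-like cells. Glycolysis and MYC targets lay at -0.19, with Slc2a3 at -0.56 and Tpi1 at -0.50, unfolded protein and integrated stress response genes at -0.18, G2 and M phase genes at -0.16 and TCR and agonist signalling genes at -0.16. The agonist list turned to 0.06 with the looser cell filter, and at resolution 0.5 the G2 and M phase list turned to 0.03 and the unfolded protein list lay at 0.00. In the agonist list Nr4a2 and Bhlhe40 were lower while Cd200 (0.99) and Relb (0.56) were higher, and in the unfolded protein list Herpud1 was higher (0.46). Thymocyte maturation and egress genes lay at 0.16 (percentile 99.99), with the IL-7 receptor gene Il7r at 0.77, Klf2 at 0.47 and the egress receptor gene S1pr1 at 0.36, while Slfn2 was lower (-0.33) and 1 of 20 members was at least 1.5-fold higher. The V(D)J recombination and DP program lay at 0.31, the DN and Notch program at 0.30 and cholesterol and lipid synthesis at 0.20. The DP list turned to -0.02 with the stricter cell filter, the DN list to -0.08 with means of per-cell CPM and -0.03 without cells holding Ptcra, Dntt, Rag1 or Rag2 UMIs, and the cholesterol list to -0.03 at resolution 2. The free RNA and other cell types list lay at -0.10.

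The interferon-stimulated list in Treg-like cells lay at -0.08 (percentile 0.98), with Bst2 at -0.56, and turned to 0.07 in the Treg-like clusters of the mature subset. The remaining lists in this class lay inside the middle 95% of random lists: the Treg signature at 0.04, where Cd83 was lower and Itgae higher (0.77), IL-2 and STAT5 response at 0.07, proximal TCR signalling components at 0.06, oxidative phosphorylation at 0.05, chemokine receptors and adhesion at 0.07, S phase at -0.01, apoptosis regulators at -0.04, p53 targets at -0.09, type 1 effector genes at -0.09 and genes derived from retroviral elements at -0.16 over 3 members. Germline genes had fewer than 3 members with 20 UMIs in each of the 4 classes and gave no median. Fc receptors and adaptors had 3 such members in DN-like cells alone, where they lay at 0.06. After thinning, 5.45% of WT and 3.85% of cKO Treg-like cells held an Mki67 or Top2a UMI, genes of dividing cells, a ratio of 0.706 (0.359 to 1.37). With at least 2 UMIs, 1 of 422 and 3 of 468 cells remained, a ratio of 2.71 (0.217 to 142.0), so no direction was detectable at this depth. In all kept cells the shares were 23.1% and 19.98% (ratio 0.865, 0.801 to 0.933), which pools classes whose own shares differed between the libraries. With at least 1 UMI the interval also included 1 in Treg precursor-like (0.584 to 1.57), DP-like (0.6335 to 1.17) and DN-like cells (0.696 to 1.31). With at least 2 UMIs it excluded 1 in DP-like cells, at 13 of 1593 WT and 5 of 1981 cKO cells (ratio 0.309, 0.0863 to 0.9245). It included 1 in Treg precursor-like (0.620 to 2.21) and DN-like cells (0.568 to 4.07). Clusters with cycle genes among their top genes had no class name and lay outside these classes. They held 430, 474, 211 and 461 WT cells and, in the same order, 309, 360, 234 and 392 cKO cells. The shares within classes thus leave out many dividing cells and cannot decide whether cKO cells divided less.

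**Figure D3:**
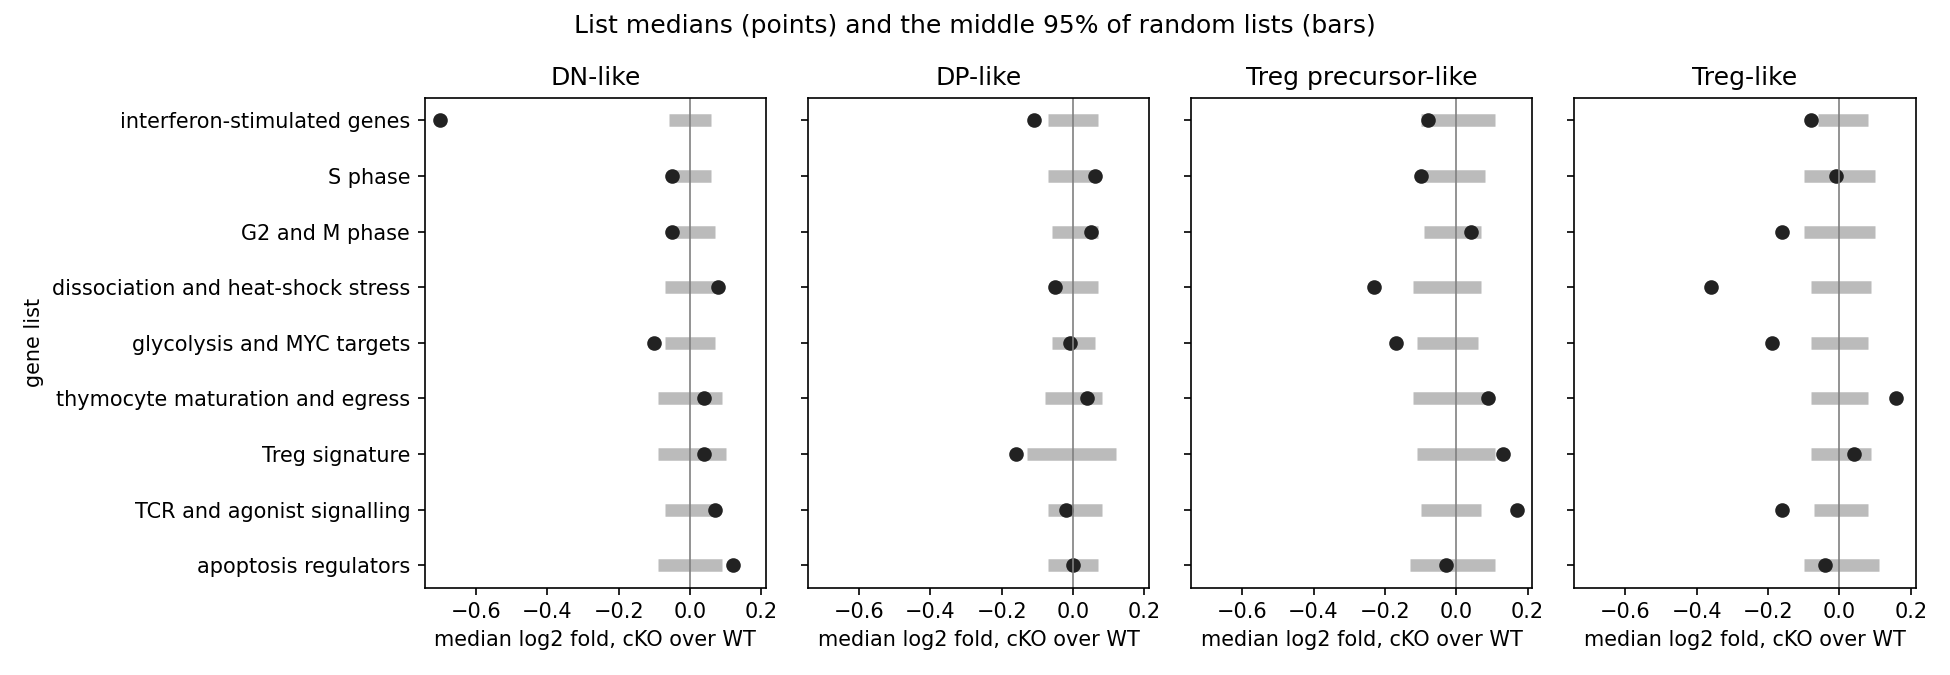
Median log2 fold of cKO over WT for 9 gene lists (y axis) in 4 classes (panels), relative to all genes (points), with the middle 95% of random lists (bars). The interferon-stimulated list lay at -0.70 in DN-like and -0.08 in Treg-like cells, and heat-shock stress genes at -0.36 in Treg-like cells.

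Setdb1 (ENSMUSG00000015697) RNA did not differ detectably at this depth in Treg-like cells, at 22.3 CPM in WT and 25.8 CPM in cKO (ratio 1.16, 0.815 to 1.65). Across 20 alternatives its log2 fold ranged from -0.23 to 0.44. It stood at 32.3 and 34.1 CPM in DN-like cells, at 29.4 and 28.6 CPM in DP-like cells, and at 34.3 and 19.7 CPM in Treg precursor-like cells, from 81 and 38 UMIs (ratio 0.576, 0.381 to 0.856). Setdb2 stood at 5.32 and 8.73 CPM in Treg-like cells, from 15 and 25 UMIs. A 3′ tag outside deleted exons is still counted, so these levels do not check the deletion.

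Treg precursor-like cells, 175 in WT and 191 in cKO, shared part of the Treg-like set. Highest under the rule for named genes were the glutathione transferase gene Gsta4 (log2 1.67), Ssbp4 (1.55), Resf1 (1.51) and the transporter gene Slc16a6 (1.37). Next came the glucocorticoid-induced leucine zipper gene Tsc22d3 (1.24), Gstt2 (1.13), Atf7ip (1.05), Ddt (0.86), Zfp36l2 (0.77) and Tmem131l (0.75). Lowest under the same rule were Cd8a (-0.75), the creatine kinase gene Ckb (-0.75), the cyclin gene Ccnb1 (-0.74), Hopx (-0.71) and Ybx3 (-0.71). Then came Hsph1 (-0.68), Exosc9 (-0.65), the mitochondrial chaperone gene Hspd1 (-0.63), Pou2f2 (-0.62) and Gng2 (-0.61). TCR and agonist signalling genes lay at 0.17 (percentile 99.99), but 0 of its 30 members were at least 1.5-fold higher and 2, Egr3 (-1.07) and Irf4 (-0.57), were at least 1.5-fold lower. Nfkbid and Tnfaip3 stood at 0.55, Myc at -0.56 and Id3 at -0.53. Heat-shock stress genes lay at -0.23 (percentile 0.0) and interferon-stimulated genes at -0.08 (percentile 4.39). The Treg signature lay at 0.13, although Foxp3 stood at -0.46, the DN and Notch program at 0.26, glycolysis and MYC targets at -0.17 with Slc16a3 higher (0.91), S phase at -0.10 and type 1 effector genes at -0.28. The type 1 list turned to 0.10 and the DN list to -0.18 with doublets kept. Across 15 alternatives Resf1 ranged from 0.78 to 1.97, Gstt2 from 0.21 to 1.40 and Ccnb1 from -1.19 to 0.31. Fcgr2b had 0 and 9 UMIs. Foxp3 stood at 32.6 and 22.3 CPM (ratio 0.685, 0.460 to 1.01), and its fold was above 0 under 3 of 15 alternatives. Il2ra stood at 73.2 CPM in WT and 68.5 CPM in cKO, below the 223 and 273 CPM of Treg-like cells. Cd4 stood at 85.4 and 96.0 CPM, Cd8a at 169 and 98.6 CPM, and Xcl1 at 561 and 369.5 CPM. The class name rests on agonist-signalling markers, and agonist-signalled cells other than Treg precursors are not excluded.

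DP-like cells numbered 2072 in WT and 3081 in cKO. Under the rule for named genes, the peptide transporter gene Slc15a2 was highest (17.3 and 76.1 CPM, log2 1.87). Next came Tsc22d3 (1.14), the pro-apoptotic gene Bmf (0.98), Zfp36l2 (0.82), the mTORC1 inhibitor gene Ddit4 (0.72) and the splicing regulator gene Mbnl1 (0.70). Ssbp4 (0.67), Atf7ip (0.65), the pyruvate dehydrogenase kinase gene Pdk1 (0.65) and Pik3ip1 (0.62) followed. In DN-like cells Slc15a2 (1.41), Tsc22d3 (1.31), Ssbp4 (1.10), Bmf (0.83), Zfp36l2 (0.80) and Ddit4 (0.60) were higher in cKO too. Pik3ip1 (0.39), Mbnl1 (0.35), Pdk1 (0.19) and Atf7ip (-0.01) had smaller folds there. A shift of the whole library was not tested for these DP-like genes. By the same rule Phlda1 was lowest (88.8 and 39.5 CPM, -1.07), followed by the interferon-inducible gene Ifi27 (-0.69), Insl5 (-0.69) and Ly6k (-0.63). Then came the histone gene Hist1h2ap (-0.61), the lactate transporter gene Slc16a1 (-0.51), Dtl (-0.49), Isca1 (-0.42), Lrwd1 (-0.41) and Pxmp4 (-0.41). The interferon-stimulated list lay at -0.11 (percentile 0.05), with Ifi27l2a at -1.11, and the Treg signature at -0.16 (percentile 0.945). The free RNA and other cell types list lay at -0.19 over 4 members (percentile 1.47), and turned to 0.08 with doublets kept and 0.55 with the stricter cell filter. Fcgr2b had 0 UMIs in WT and 24 in cKO DP-like cells, at least 5.85-fold higher against the floor, and the exact interval of the ratio starts at 4.40.

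In DN-like cells, 1208 in WT and 793 in cKO, interferon-stimulated genes were lower in cKO. The list lay at -0.70 (percentile 0.0), with 22 of 38 members at least 1.5-fold lower and 0 at least 1.5-fold higher. The lowest genes under the rule for named genes were the ubiquitin-like modifier gene Isg15 (238 and 62.8 CPM, log2 -1.84), Ifit1 (-1.84) and Ifitm3 (-1.81). Then came Oasl2 (-1.74), the interferon regulatory factor gene Irf7 (-1.50), Rtp4 (-1.38), Ly6k (-1.19), Ifi27 (-1.12), the imprinted non-coding gene H19 (-0.87) and Rnf213 (-0.82). One DN-like cluster with interferon-stimulated genes as its top genes held 9.02% of WT (109 of 1208) and 1.39% of cKO DN-like cells (11 of 793). Without this cluster, a choice made after the data had been seen, the list lay at -0.42.

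Higher in cKO DN-like cells were Rasa4 (log2 2.13), the class Ib MHC genes H2-Q7 (2.12) and H2-Q4 (0.85), Tsc22d3 (1.31), the proton-sensing receptor gene Gpr65 (1.18), the survival gene Bcl2 (145 and 319 CPM, 1.11), Ssbp4 (1.10), Sap30 (1.07), the clock gene Per1 (1.03) and Bmf (0.83). Apoptosis regulators lay at 0.12 (percentile 99.54), with Bcl2l11 at 0.60. Unfolded protein and integrated stress response genes lay at -0.15, although Herpud1 was higher (0.64), glycolysis and MYC targets at -0.10, cholesterol and lipid synthesis at -0.09, which lay at 0.00 at resolution 0.5, and proximal TCR signalling components at 0.08. Heat-shock stress genes lay at 0.08 while Hsph1 stood at -1.15, and turned to -0.03 at resolution 0.5. Cd4 (0.61), Cd8a (0.59) and Cd8b1 (0.58) were higher as well, with Cd8a at 10.5 CPM in WT and 18.2 CPM in cKO. Cd4 stood at 3.20 CPM in WT and 7.55 CPM in cKO, from 33 and 48 UMIs (ratio 2.36, 1.48 to 3.79). The cause was not tested, and these differences limit the use of DN-like cells as the comparator formed before the deletion. Tsc22d3, Ssbp4, Zfp36l2 and Slc15a2 had folds above 0.60 in each of the 4 classes, and Slc15a2 stood at 1.41 in DN-like and 1.76 in Treg-like cells.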

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

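Of 3947 values of 223 results under other settings, 3569 stayed inside the interval or spread of the reported value, 338 moved beyond it and 40 turned in direction. A value was counted as turning only where the reported interval excluded no change, or the list lay outside the middle 95% of random lists. Another 208 values lay on the other side of no change from a reported value that did not meet this. The cause was not tested for any value below. The automatic doublet thresholds, other thinning depths, mature-subset versions, sex-gene version, other Leiden seeds, the removal of cells with Ptcra, Dntt, Rag1 or Rag2 UMIs and of the interferon-high cluster were chosen after the data had been seen. The 10 highest named genes of Treg-like cells stayed above 0 in all 20 alternatives, with Resf1 between 2.27 and 2.73 and Atf7ip between 1.06 and 1.38. The Treg-like border was fragile: replacing 1 of 2000 variable genes gave 604 WT and 667 cKO cells in place of 439 and 483, and the other seeds gave 410 and 476 or 359 and 401. Its share ratio ranged from 1.02 to 1.18 among kept cells, was 0.967 without DN-like cells, and ranged from 0.559 to 1.001 in the mature subset. The effector Treg-like ratio in the mature subset ranged from 0.181 to 0.427, but the 2 other seeds gave no such cluster and so no value. Settings that only redraw clusters cannot move shares of all kept cells and were not counted for them. Germline genes gave no value. At 1 library per genotype, depth limits only the counting error.

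For shares, the Treg-like ratio in the mature subset was 0.559 with all variable genes and turned to 1.001 with classes defined on WT cells. The DP-like ratio was 1.17 with the stricter cell filter and 1.31 without DN-like cells. The DN-like ratio was 0.694 with doublets kept, 0.727 at resolution 0.5 and 0.708 without differing and cycle genes. The effector Treg-like ratio in the mature subset was 0.427 with classes defined on WT cells. The Foxp3 ratio in all kept cells was 1.35 when thinned to 3000 UMIs. The Mki67 or Top2a ratio was 0.962 in all kept cells at 3000 UMIs, and with at least 2 UMIs 2.71 in Treg-like and 1.52 in DN-like cells. In DP-like cells, not counted among these results, it was 0.309 with at least 2 UMIs.

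Values that turned in direction in Treg-like cells were, with the looser filter, Cd8a (-0.29), Cd8b1 (-0.05) and TCR and agonist signalling (0.06); with the stricter filter, Penk (1.11), V(D)J recombination and DP program (-0.02) and H3K9 methylation and HUSH machinery (-0.03). At resolution 0.5 they were Pglyrp1 (0.02), Cd8a (-0.41), Cd8b1 (-0.10), G2 and M phase (0.03) and unfolded protein and integrated stress response (0.00), and at resolution 2 Penk (0.13) and cholesterol and lipid synthesis (-0.03). With sex genes left out they were Cd8a (-0.35) and Cd8b1 (-0.05). The DN and Notch program turned with means of per-cell CPM (-0.08) and without cells holding Ptcra, Dntt, Rag1 or Rag2 UMIs (-0.03), and the interferon-stimulated list in the Treg-like clusters of the mature subset (0.07).

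In Treg precursor-like cells Ccnb1 turned with the stricter filter (0.31) and Leiden seed 1 (0.01), Bcl2l11 with the stricter filter (-0.05), and Bcl2 with means of per-cell CPM (-0.10) and in cells without Mki67 or Top2a UMIs (-0.45). Type 1 effector genes turned with doublets kept (0.10), with Leiden seed 2 (0.08) and in cells without Mki67 or Top2a UMIs (0.03), where glycolysis and MYC targets also turned (0.02). The DN and Notch program turned with doublets kept (-0.18) and with members of 1 UMI (-0.14), and S phase with the automatic doublet thresholds (0.08). In DP-like cells the free RNA and other cell types list turned with the stricter filter (0.55), doublets kept (0.08), without differing and cycle genes (0.07), with sex genes left out (0.18) and with WT-defined classes (0.09). In DN-like cells heat-shock stress genes turned with the looser filter (-0.01), at resolution 0.5 (-0.03) and without differing and cycle genes (-0.01), and cholesterol and lipid synthesis at resolution 0.5 (0.00).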

Other observations

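In the mature subset, a cluster with Xcl1, Ncr1 and Klrd1 among its top genes numbered 4 of 872 in WT and 19 of 1070 in cKO (share ratio 3.87, 1.29 to 15.7). A Trac UMI was held by 6 of its 23 cells and by 663 of 765 Treg-like cells of the subset, and an Ncr1 UMI by 14 and 0, so it is not called a T cell cluster here. Gamma-delta T-like cells numbered 8 and 20 (2.04, 0.860 to 5.35). CD4 SP-like cells, the single-positive stage, numbered 70 and 99, too few for folds. Among the highest genes of DN-like cells, H2-Q7 and H2-Q4 lie with 1 protein-coding gene between them on GRCm38.

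The tests of a shift of the whole library, of an effect that starts with CD4-Cre, of another mix of the clusters themselves and of WT cells brought to the depths of the cKO cells were chosen after the results they measure had been seen. The depth test first took Foxp3 from unthinned cells and argued against depth. It was corrected after that result had been seen, and the use of 100 thinnings was chosen then. The other tests were written first, but the clustering was redone after their first results were known.

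The 10 named genes highest in cKO Treg-like cells had a median log2 fold of 2.07. Doublets with DN or DP cells are argued against, since without Treg-like cells holding a Ptcra, Dntt, Rag1 or Rag2 UMI (47 WT and 58 cKO cells) the median was 2.10. For the 6 of these genes with at least 100 UMIs in DN-like cells, a shift of the whole library is argued against: their median was 1.92 in Treg-like and 0.06 in DN-like cells, with Resf1 the highest at 0.49. The median of all 10 in DN-like cells, 0.00, decides nothing for Cfap53, Krt83, Dapl1 and Zfp52, which had fewer than 100 UMIs there. A candidate explanation is loss of the floxed gene, but strain variants near it or differences between the mice of 1 library each were not tested and stay open.

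Cells named effector Treg-like were fewer in the cKO mature subset. Without clusters, 24 of 331 WT and 5 of 329 cKO Foxp3-positive T-lineage cells held a Klrg1 or Il1rl1 UMI, a ratio of 0.210 (0.0625 to 0.560). This argues against cluster borders as the whole cause, although no background share of these UMIs in other cells is given. Klrg1 and Il1rl1 were among the top genes of the effector Treg-like cluster itself. Less RNA of these genes per cell would give the same ratio, so the count cannot tell this from fewer effector cells. Lower depth of the cKO cells is argued against: with WT cells brought to the depths of the cKO cells (medians of 5872 and 5288 UMIs before), the median ratio over 100 thinnings was 0.208 and the highest upper end of an interval 0.606. With all cells thinned to 2000 UMIs the median ratio was 0.236 and the highest 0.562, but with fewer positive cells left the upper end was below 1 in only 68 of 100 thinnings. Such cells may recirculate to the thymus with age, and the mice's age is not given, so a difference between mice or in bead enrichment stays open beside the genotype.

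Interferon-stimulated genes were lower in cKO DN-like cells. Of 13 clusters with 100 cells of each library, 10 had the list below the 2.5th percentile of random lists, at -0.45 to -0.08. The other clusters were the DP-like clusters 1 (-0.10) and 2 (0.01) and the Treg precursor-like cluster 12 (-0.08). Medians of -0.45 to -0.36 lay in the DN-like cluster 4 and the unnamed clusters 3, 5, 6, 13 and 14. The Treg-like cluster 11 counted among the 10 at -0.08. The list lay at percentile 0.0 in DN-like cells. This argues against an effect of CD4-Cre inside each cell only if DN-like cells had formed before that step, which was not measured. Cd4 RNA was also higher in cKO DN-like cells (ratio 2.36, 1.48 to 3.79). Whether later cells pass an effect on to DN-like cells cannot be decided by this test, which measures only the DN-like cells. A different mix of the clusters themselves is argued against by the low medians inside 76.92% of them. Another mix of finer cell states inside clusters cannot be told apart: the list was below 0 in 92.31% of clusters, which a single cluster could undo, and such a mix would lower medians inside clusters too. Without the interferon-high DN-like cluster (109 WT and 11 cKO cells) the list lay at -0.42 in place of -0.70, a move toward 0 that is fixed by the genes that define the cluster. A difference between the mice, such as exposure to infection, could give this pattern and was not tested.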
